A study of Arabidopsis thaliana with 30 samples.

How the data were processed

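Poly(A) RNA of whole seedlings had been sequenced in read pairs on an Illumina NovaSeq X Plus. The authors deposited a matrix of 27655 genes by 30 libraries, and its header records featureCounts 2.0.3 with read pairs counted without regard to strand and pairs that map to several places given to each of them in part. The deposited values are therefore expected counts, made by the authors with featureCounts as fractional read-pair counts and not scaled, and 6.31% of them were not whole. The authors' notes name HISAT2, SAMtools, featureCounts, DESeq and DESeq2 and the genome build TAIR10. Values were rounded to whole counts, and all 30 columns were used. Near-identical genes share read pairs, so values of such genes are uncertain. Of the identifiers 27445 matched a locus of the TAIR10 reference, and the 122 mitochondrial ones did not match but were kept, as were 88 plastid genes. Poly(A) selection leaves organelle transcripts poorly sampled, and they were not interpreted.

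Groups followed the labels: genotype, treatment and time, with 3 replicates each. The labels do not say whether replicates were separate cultures or harvests, so p-values measure only the spread between these samples. They name the time as the batch, so AA was compared with MS at the same time, and MS against untreated carries time and batch with it. Replicate numbers were checked for pairing: libraries with the same number were no closer across groups than others (mean correlation of residuals -0.004 against 0.002), so samples were taken as unpaired, and a fit with replicate number as a block was an alternative.

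Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 21256. Counts were scaled by TMM factors (0.958 to 1.058). A negative binomial model with a mean per group was fitted to all 30 libraries, and 21 comparisons were tested with edgeR's quasi-likelihood F test in edgeR 4.0.16 under R 4.3.3 (biological coefficient of variation 11.2%, prior degrees of freedom 9.35). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Log2 CPM for display used a prior count of 2. A fold against a group at 0 counts was set as a bound at 3 counts per library. Total counts set the precision, and counting error is not the spread between seedlings.

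There were 24 gene lists, with 342 places for 326 genes, written from textbook knowledge and matched to the file by locus code, and none was left out. Each list was tested with limma 3.58.1's camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison, and again with an estimated correlation, with fry and with replicate number as a block. Of the 115 list tests described, 95 passed.

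Lists, comparisons and the rule for naming genes were chosen before the data were examined, as were tests and alternatives apart from those named below. The rule took up to 6 genes per direction with the largest change among those that passed, with at least 5 CPM in the higher group and, for comparisons of a pair of groups, no overlap of libraries. It added up to 4 members of each list described, by smallest adjusted p, and fixed genes: EIN2 in genotype comparisons, AOX1A, UPOX, OM66, NDB4, CYP81D8, UGT74E2, ANAC013 and ANAC017 in AA comparisons, ERF1, EBF2, PDF1.2A, CHI-B and HEL in AA and genotype comparisons, and ADH1, PDC1, HRE1 and PCO1 in MS comparisons. Of the genes it allows, the text names some, and apart from fixed genes none whose call was lost without a library.

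The size of the AA response was the mean, over genes called for the AA effect averaged over genotypes, of each AA library's log2 difference from the mean of its MS group, signed by that effect, and was compared between genotypes with an exact permutation test (two-sided). The same code was tested on simulated data with planted changes. For AA against MS in wild type at 3 h it recovered 50.7%, 71.6% and 92.4% of changes of 1.5-, 2- and 4-fold with 6.54% of calls on unchanged genes. For the AA by genotype interaction at 3 h these were 21.2%, 69.7% and 84.8% with 3.33%, and for ein2-5 against wild type, untreated, 55.2%, 86.4% and 93.8% with 4.32%.

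Alternatives were RLE and upper-quartile factors, no count filter, 1 CPM in 3 libraries, DESeq2 1.42.0, an adjusted p under 0.01, fits of only the libraries compared, a replicate block, organelle genes left out, and each library left out in turn. After seeing the data, list tests without replicate 3 of ein2-5 with MS at 3 h, the hypoxia list of AA against untreated and tests of adjacent genes and of chromosomes were added. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not used.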

Results

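Messenger RNA was measured in whole Arabidopsis thaliana seedlings 12 days old, in Col-0 wild type and in ein2-5, a mutant that lacks a working EIN2, which carries the ethylene signal towards the nucleus. The seedlings were covered with liquid Murashige and Skoog medium (MS) or with MS that held 20 µM antimycin A (AA), an inhibitor of complex III of the respiratory chain, and were collected after 3 h or 24 h. Other seedlings of each genotype were left untreated. Each of the 10 groups held 3 libraries, 30 in all, and the total count of a library ranged from 21.2 to 32.6 M read pairs (median 24.3 M). Transcript of EIN2 (AT5G03280) itself lay between 105 and 118 CPM (counts scaled to library size) in the wild-type groups and between 39.0 and 45.7 CPM in the ein2-5 groups.

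Changes are log2 fold changes ± SE from 1 fit to all 30 libraries, levels are mean CPM ± SD of 3 libraries, and adjusted p-values of genes come from edgeR's quasi-likelihood test. Gene lists were tested against all other genes with camera at a preset correlation of 0.01. Estimated correlations, mostly higher, gave lists that passed larger p-values, printed where a list then failed. A list is described by the number of its tested members that passed over all 21256 genes and, where this differs, by the number that passed when adjusted over the list alone.

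**Figure D1:**
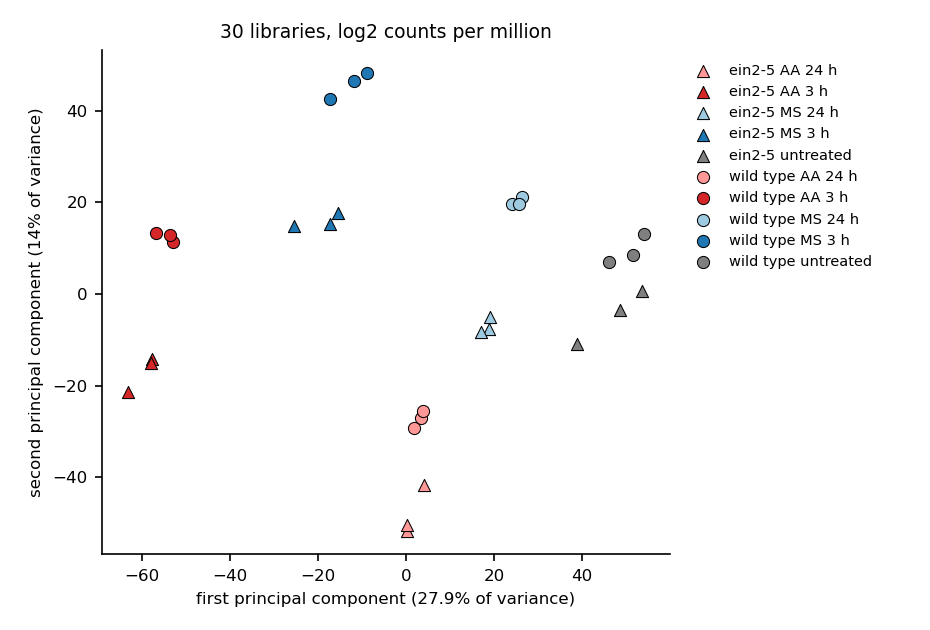
Principal components of the log2 CPM of the 30 libraries, with component 1 (27.9% of the variance) on the horizontal axis and component 2 (14% of the variance) on the vertical axis. Each point is 1 library, and the libraries with AA at 3 h lie between -63.1 and -52.9 on component 1, the untreated ones between 38.9 and 54.0.

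AA was compared with MS in wild type at 3 h to see which transcripts answer a block of complex III early. Transcripts that mark mitochondrial dysfunction had the highest median of the 24 lists: AOX1A (AT3G22370), the alternative oxidase that takes electrons from ubiquinol without complex III, went from 57.9 ± 1.88 to 339 ± 34.9 CPM (2.55 ± 0.15, adjusted p = 3.16e-14, n = 3 libraries per group). ANAC013 (AT1G32870), a membrane-bound transcription factor that activates such genes, rose by 2.79 ± 0.16 (adjusted p = 4.30e-14), and UPOX (AT2G21640), a small mitochondrial protein induced by oxidants, rose by 3.87 ± 0.27 (adjusted p = 2.64e-12). OM66 (AT3G50930), an ATPase of the outer mitochondrial membrane, rose by 3.17 ± 0.27, NDB4 (AT2G20800), an external NAD(P)H dehydrogenase, by 4.43 ± 0.49, CYP81D8 (AT4G37370), a cytochrome P450, by 3.87 ± 0.31, UGT74E2 (AT1G05680), a glucosyltransferase, by 3.45 ± 0.55, and ABCB4 (AT2G47000), an auxin transporter, by 3.31 ± 0.18, with adjusted p-values of 2.78e-05 or less. In all, 21 of 22 mitochondrial dysfunction genes rose and none fell (median 3.14, adjusted p = 2.44e-45). ANAC017 (AT1G34190), a related factor of mitochondrial stress, stood at 55.2 ± 1.07 CPM against 52.8 ± 0.504 (0.06 ± 0.07, adjusted p = 0.699).

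Several other lists, some sharing genes with the mitochondrial dysfunction list, rose in wild type at 3 h of AA. Of the tau-class glutathione transferases 7 of 8 rose (median 1.82, adjusted p = 2.00e-16), among them GSTU25 (AT1G17180, 3.11 ± 0.20) and GSTU22 (AT1G78340, 2.27 ± 0.14). Of the auxin-responsive genes, 6 of 9 rose, 7 adjusted over the list alone (median 1.02, adjusted p = 8.93e-16), led by GH3.3 (AT2G23170), which went from 11.7 ± 2.23 to 293 ± 35.9 CPM (4.64 ± 0.15), and GH3.2 (AT4G37390, 4.44 ± 0.12), enzymes that join auxin to amino acids. Touch and early stress regulators rose in 7 of 14 cases, 9 adjusted over the list alone (median 0.99, adjusted p = 4.82e-12). OXI1 (AT3G25250), a kinase activated by oxidants, stood at 3.22 ± 0.13 and ZAT12 (AT5G59820) at 2.14 ± 0.16. Among genes of sugar starvation, 8 of 11 rose, 9 adjusted over the list alone (median 0.67, adjusted p = 6.42e-14), such as BGLU30 (AT3G60140), a dark-induced beta-glucosidase (5.18 ± 0.31), and DIN10 (AT5G20250, 1.0 ± 0.12). The alternative respiration list had 7 of 14 members higher (median 0.92, adjusted p = 8.68e-07), including NDB2 (AT4G05020, 1.56 ± 0.21), and adjusted over the list alone 7 were higher and 1 lower. Of the ANAC017-related factors 2 of 5 rose, 3 adjusted over the list alone (adjusted p = 8.68e-07). ANAC053 (AT3G10500) stood at 1.64 ± 0.09. Also 6 of 14 mitochondrial chaperones, proteases and import proteins rose (adjusted p = 0.00109, or 0.2 with an estimated correlation). The chaperone MTHSC70-1 (AT4G37910) stood at 1.12 ± 0.12.

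Transcripts of low oxygen fell at the same time. Of the core hypoxia genes 17 of 27 fell and 2 rose, the latter 3 adjusted over the list alone (median -0.89, adjusted p = 1.86e-19). SUS4 (AT3G43190), a sucrose synthase, went from 115 ± 14.7 to 30.1 ± 1.1 CPM (-1.93 ± 0.10). SAD6 (AT1G43800), a fatty acid desaturase, changed by -2.34 ± 0.14, HRA1 (AT3G10040), a repressor of hypoxia factors, by -2.31 ± 0.15, and HUP9 (AT5G10040) by -5.45 ± 0.41, each with an adjusted p of 1.90e-11 or less. Iron deficiency genes fell in 3 of 7 cases (median -0.69, adjusted p = 0.00767, or 0.292 with an estimated correlation). FIT (AT2G28160), the regulator of iron uptake, stood at -1.28 ± 0.14 and IRT1 (AT4G19690), the iron transporter, at -1.27 ± 0.21. Root and root hair markers fell in 3 of 13 cases (median -0.15, adjusted p = 0.014, adjusted p = 0.0618 with an estimated correlation), as in EXPA7 (AT1G12560), a root hair expansin (-1.18 ± 0.20), and COBL9 (AT5G49270, -1.15 ± 0.23).

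In wild type at 3 h, salicylic acid genes were higher in 3 of 16 members, 7 adjusted over the list alone (median 0.34, adjusted p = 0.00418, adjusted p = 0.292 with an estimated correlation). Senescence genes were higher in 2 of 11, 3 adjusted over the list alone (adjusted p = 0.0265, or 0.229 with an estimated correlation). Nuclear photosynthesis genes had a median of -0.14 with 0 of 20 members passing on their own, 6 at an unadjusted p under 0.05 and 1 with DESeq2 (adjusted p = 0.00599, adjusted p = 0.52 with an estimated correlation). The other lists did not pass. Ethylene-responsive genes had 4 of 20 members higher and 3 lower, adjusted over the list alone 5 and 3 (median 0.24, adjusted p = 0.185). Ethylene biosynthesis had 4 higher and 1 lower of 13 (adjusted p = 0.243). Ethylene perception and signalling had 1 higher and 1 lower of 13, adjusted over the list alone 2 and 1, with a median of -0.03, a mean of 0.04 and a test that pointed up (adjusted p = 0.735). Circadian clock genes were higher in 2 of 11 (adjusted p = 0.131) and abscisic acid and drought genes lower in 2 of 17 (adjusted p = 0.271). Heat shock genes were lower in 1 of 17, with 2 higher when adjusted over the list alone (median 0.16, or 0.14 with its member at 0 counts set to its bound, adjusted p = 0.247). None of the 16 respiratory chain genes (adjusted p = 0.735), 8 antioxidant enzymes (adjusted p = 0.621), 19 jasmonate genes (adjusted p = 0.894) or 8 cell cycle genes (adjusted p = 0.483) passed, with 1, 0, 2 and 0 at an unadjusted p under 0.05 and 0 called by DESeq2. Of the markers of ethylene signalling fixed beforehand, CHI-B (AT3G12500), a basic chitinase, stood at -0.42 ± 0.11 (adjusted p = 0.0132), a call lost without AA replicate 3 (adjusted p = 0.121) or MS replicate 3 (adjusted p = 0.0615). ERF1 (AT3G23240, 1.19 ± 0.63), EBF2 (AT5G25350, 0.37 ± 0.14), PDF1.2A (AT5G44420, 0.84 ± 0.41) and HEL (AT3G04720, 0.03 ± 0.16) had adjusted p-values of 0.0904 or more, though PDF1.2A passed without AA replicate 3 (adjusted p = 0.048) and EBF2 in a fit of these libraries alone (adjusted p = 0.00894).

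Across all genes, 2125 of 21256 differed between AA and MS in wild type at 3 h, 1317 higher and 808 lower, and 808 of them by at least 2-fold. AT3G54530 rose from 0 counts in all 3 MS libraries to 38.2 ± 11.5 CPM with AA, at least 299.9-fold higher against a floor of 3 counts per library. Other strong rises were those of AT3G54520 (6.96 ± 0.71), AT5G55150 (6.37 ± 0.58), AT5G24640 (6.09 ± 0.50), AT2G32020 (5.65 ± 0.28) and the transporter DTX3 (AT2G04050, 5.28 ± 0.60). Strong falls were those of AT2G17850 (-4.24 ± 0.30), WIP4 (AT4G10270, -3.12 ± 0.39) and the near-identical pair AT4G12510 (-3.63 ± 0.21) and AT4G12520 (-3.39 ± 0.18). That pair shares read pairs, so its values are uncertain.

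**Figure D2:**
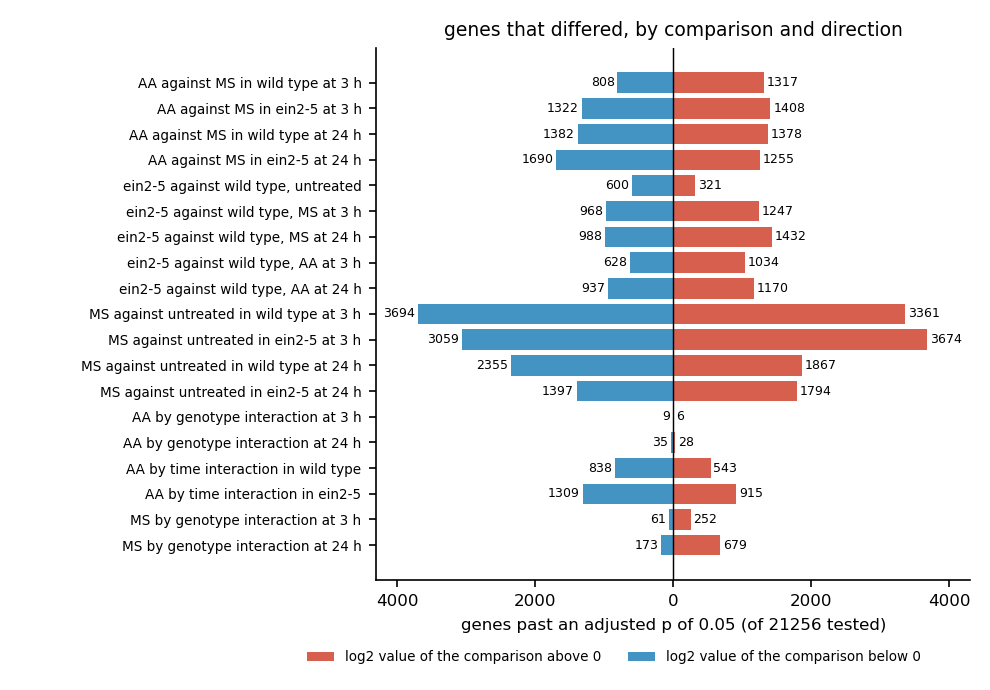
Number of genes that passed the test (horizontal axis), with a bar per comparison to the right for log2 values above 0 and to the left for those below. MS against untreated at 3 h has the longest bars (3361 and 3694 genes in wild type), and the AA by genotype interaction at 3 h the shortest (6 and 9).

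AA was then compared with MS in ein2-5 at 3 h, where ethylene signalling is blocked. AOX1A went from 59 ± 14.2 to 435 ± 9.19 CPM (2.88 ± 0.15, adjusted p = 2.43e-15), and all 22 mitochondrial dysfunction genes rose (median 3.08, adjusted p = 1.11e-44). UPOX rose by 3.96 ± 0.26, NDB4 by 4.6 ± 0.44, CYP81D8 by 3.58 ± 0.30, UGT74E2 by 3.45 ± 0.54, ABCB4 by 3.2 ± 0.18, OM66 by 2.95 ± 0.26 and ANAC013 by 2.6 ± 0.16, with adjusted p-values of 1.96e-05 or less, and ANAC017 stood at 0.09 ± 0.07 (adjusted p = 0.489). Tau-class glutathione transferases rose in 7 of 8 cases (median 1.69, adjusted p = 4.77e-14), auxin-responsive genes in 7 of 9 (median 1.17, adjusted p = 6.18e-13), touch and early stress regulators in 10 of 14 (median 1.26, adjusted p = 6.18e-13) and sugar starvation genes in 7 of 11 (median 0.38, adjusted p = 1.54e-06). GH3.3 rose by 4.39 ± 0.15, GH3.2 by 3.83 ± 0.12, OXI1 by 3.35 ± 0.13, ZAT12 by 2.76 ± 0.16, BGLU30 by 4.2 ± 0.28 and DIN1 (AT4G35770), a senescence-associated protein induced in the dark, by 1.16 ± 0.23. Core hypoxia genes fell in 16 of 27 cases and rose in 4, 17 and 5 adjusted over the list alone (median -0.65, adjusted p = 1.12e-11, or 0.0451 with an estimated correlation, as for sugar starvation genes). SUS4 stood at -1.66 ± 0.10, HRA1 at -1.96 ± 0.14 and SAD6 at -1.66 ± 0.14.

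In ein2-5 at 3 h, of the ethylene-responsive genes 4 of 20 rose and 2 fell, 6 and 3 adjusted over the list alone (adjusted p = 0.0385, or 0.26 with an estimated correlation). Of its transcription factors, EDF2 (AT1G68840) stood at 0.95 ± 0.10, ERF2 (AT5G47220) at 0.98 ± 0.18 and EDF1 (AT1G25560) at 0.75 ± 0.12. ACS6 (AT4G11280), an enzyme of ethylene synthesis, rose by 1.67 ± 0.15, and ACO1 (AT2G19590), which makes ethylene in the last step, changed by -0.94 ± 0.11. CHI-B fell by 0.54 ± 0.11 on the log2 scale (adjusted p = 0.000864), and ERF1 (-0.22 ± 0.85), EBF2 (0.19 ± 0.14), PDF1.2A (0.45 ± 0.49) and HEL (0.13 ± 0.16) had adjusted p-values of 0.473 or more. The test called 2730 genes, 1408 higher and 1322 lower, 852 of them by at least 2-fold, although upper-quartile factors gave 1267 higher and 1615 lower and these libraries alone 1728 genes. AT3G54530 (7.92 ± 0.33), AT4G28460 (6.92 ± 0.55), AT5G24640 (6.05 ± 0.46) and AT2G38823 (5.65 ± 0.23) rose strongly, and AT2G17850 (-3.68 ± 0.27), HUP9 (-3.64 ± 0.29) and the extensin EXT13 (AT5G35190, -2.92 ± 0.25) fell strongly. MS replicate 3 of ein2-5 at 3 h stood apart from the other libraries of its group (chi-square per degree of freedom of up to 35.9, against 21.2 or less for pairs in other groups), and every list named for this comparison kept its call without it.

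After 24 h in wild type, the mitochondrial dysfunction genes were still higher with AA: 19 of 22 rose (median 1.84, adjusted p = 1.94e-22), AOX1A from 35.9 ± 0.644 to 131 ± 9.04 CPM (1.87 ± 0.15, adjusted p = 1.01e-10). NDB4 rose by 3.71 ± 0.46, UPOX by 2.28 ± 0.23, CYP81D8 by 2.27 ± 0.33, ANAC013 by 1.82 ± 0.16 and OM66 by 1.59 ± 0.30, with adjusted p-values of 0.000303 or less, while ANAC017 stood at 50.6 ± 4.81 CPM with AA and 50.7 ± 3.27 CPM with MS. UGT74E2 rose by 2.05 ± 0.55 (adjusted p = 0.0119), a call lost without MS replicate 1 (adjusted p = 0.0548) or MS replicate 3 (adjusted p = 0.0633). Of the mitochondrial chaperones, proteases and import proteins 10 of 14 rose, 12 adjusted over the list alone (median 0.56, adjusted p = 2.63e-10). The small heat shock protein HSP23.5 (AT5G51440) stood at 2.63 ± 0.38, the co-chaperone MGE1 (AT5G55200) at 1.08 ± 0.12 and the protease LON1 (AT5G26860) at 0.74 ± 0.09. Iron deficiency genes rose in 4 of 7 cases, 5 adjusted over the list alone (median 4.1, adjusted p = 4.09e-08), and the regulators of iron uptake BHLH100 (AT2G41240, 5.29 ± 0.46), BHLH38 (AT3G56970, 5.25 ± 0.49), BHLH101 (AT5G04150, 4.73 ± 0.37) and BHLH39 (AT3G56980, 4.1 ± 0.31) all rose, with adjusted p-values of 3.80e-09 or less.

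Root transcripts were lower after 24 h of AA in wild type. Of the root and root hair markers 8 of 13 fell (median -1.05, adjusted p = 1.56e-07), and CASP4 (AT5G06200, -2.13 ± 0.30), CASP2 (AT3G11550, -1.07 ± 0.17) and CASP1 (AT2G36100, -1.06 ± 0.13), which place the Casparian strip of the endodermis, were among them. Core hypoxia genes rose in 12 of 27 cases and fell in 2, the former 13 adjusted over the list alone (median 0.33, adjusted p = 4.05e-06, adjusted p = 0.181 with an estimated correlation). HRE2 (AT2G47520), a hypoxia transcription factor, stood at 3.05 ± 0.33, PDC1 (AT4G33070), a pyruvate decarboxylase of fermentation, at 1.54 ± 0.12 and SUS4 at 0.88 ± 0.10. Sugar starvation genes fell in 7 of 11 cases and rose in 1, the falls 9 adjusted over the list alone (adjusted p = 2.92e-06, adjusted p = 0.0514 with an estimated correlation), as in ASN1 (AT3G47340), an asparagine synthetase (-0.98 ± 0.13), and TPS11 (AT2G18700), a trehalose phosphate synthase-like protein (-0.84 ± 0.12). Nuclear photosynthesis genes fell in 9 of 20 cases, 17 adjusted over the list alone (adjusted p = 4.10e-06, or 0.326 with an estimated correlation). Abscisic acid and drought genes fell in 3 of 17 (adjusted p = 0.00106, or 0.326 with an estimated correlation). The dehydrin COR47 (AT1G20440) stood at -1.0 ± 0.10. The iron superoxide dismutase FSD1 (AT4G25100, -0.86 ± 0.15) and the catalase CAT3 (AT1G20620, -0.67 ± 0.12) fell as well. The test called 2760 genes, 1378 higher and 1382 lower (1298 and 1287 with no count filter), 646 of them by at least 2-fold, with AT3G54530 (6.72 ± 0.40), AT5G38910 (6.57 ± 0.65), AT1G26240 (6.36 ± 0.40) and AT1G13609 (6.27 ± 0.50) among the strong rises. AT5G62340 (-3.97 ± 0.26), AGP30 (AT2G33790), a root arabinogalactan protein (-3.84 ± 0.34), and PRP1 (AT1G54970), a cell wall protein (-2.78 ± 0.26), fell strongly, as did the near-identical pair AT5G46890 (-3.76 ± 0.25) and AT5G46900 (-3.02 ± 0.19), whose values are uncertain too. EBF2 (-0.17 ± 0.14) and CHI-B (0.23 ± 0.11) had adjusted p-values of 0.198 or more.

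In ein2-5 at 24 h, 17 of 22 mitochondrial dysfunction genes rose, 18 adjusted over the list alone (median 1.88, adjusted p = 5.77e-23). AOX1A went from 31.5 ± 3.33 to 108 ± 7.42 CPM (1.77 ± 0.15, adjusted p = 5.17e-10). NDB4 rose by 3.72 ± 0.47, UGT74E2 by 2.74 ± 0.59, UPOX by 2.62 ± 0.25, CYP81D8 by 1.92 ± 0.32 and ANAC013 by 1.86 ± 0.16, with adjusted p-values of 0.00153 or less. OM66 did not pass (0.75 ± 0.26, adjusted p = 0.0536, or 0.042 without the filter on low counts and 0.000771 in a fit of these libraries alone) and ANAC017 stood at -0.03 ± 0.07. Mitochondrial chaperones, proteases and import proteins rose in 8 of 14 cases, 10 adjusted over the list alone (median 0.50, adjusted p = 1.38e-09). HSP23.5 stood at 2.49 ± 0.38 and MGE1 at 1.16 ± 0.12. Iron deficiency genes rose in 4 of 7 cases and fell in 1, the falls 2 adjusted over the list alone (median 2.86, adjusted p = 0.000167, or 0.127 with an estimated correlation). BHLH100 stood at 4.78 ± 0.42 and BHLH38 at 4.42 ± 0.43. Root and root hair markers fell in 6 of 13 cases, 7 adjusted over the list alone (median -0.62, adjusted p = 9.57e-06). Cell cycle genes fell in 3 of 8, 6 adjusted over the list alone (median -0.39, adjusted p = 0.000246). The mitotic cyclins CYCB1;1 (AT4G37490) stood at -0.95 ± 0.16 and CYCB1;2 (AT5G06150) at -0.84 ± 0.11.

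In ein2-5 at 24 h jasmonate genes rose in 7 of 19 cases, 8 adjusted over the list alone (adjusted p = 0.00017, or 0.193 with an estimated correlation). CORI3 (AT4G23600) stood at 1.43 ± 0.25 and OPR3 (AT2G06050), an enzyme of jasmonate synthesis, at 0.72 ± 0.14. Abscisic acid and drought genes rose in 5 of 17 cases and fell in 1, the former 7 adjusted over the list alone (adjusted p = 0.00367, or 0.353 with an estimated correlation). COR15A (AT2G42540), a chloroplast protein of cold and drought, stood at 1.18 ± 0.23. Core hypoxia genes did not pass as a list (1 higher and 4 lower of 27, the latter 6 adjusted over the list alone, adjusted p = 0.193). In this comparison 2945 genes passed, 1255 higher and 1690 lower, 545 of them by at least 2-fold, and without AA replicate 1 the count was 1949. AT5G24640 (7.47 ± 0.74), AT3G54530 (5.99 ± 0.43) and the Nudix hydrolase NUDT24 (AT5G19470, 4.16 ± 0.59) rose strongly, and AT5G62340 (-4.15 ± 0.27), the marneral synthase MRN1 (AT5G42600, -2.74 ± 0.48) and the beta-glucosidase BGLU21 (AT1G66270, -2.45 ± 0.13) fell strongly. CHI-B stood at 0.34 ± 0.11 (adjusted p = 0.0379), a call lost without AA replicate 2 or 3 or MS replicate 1, 2 or 3 (highest adjusted p = 0.231) and with upper-quartile factors (adjusted p = 0.0615).

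**Figure D3:**
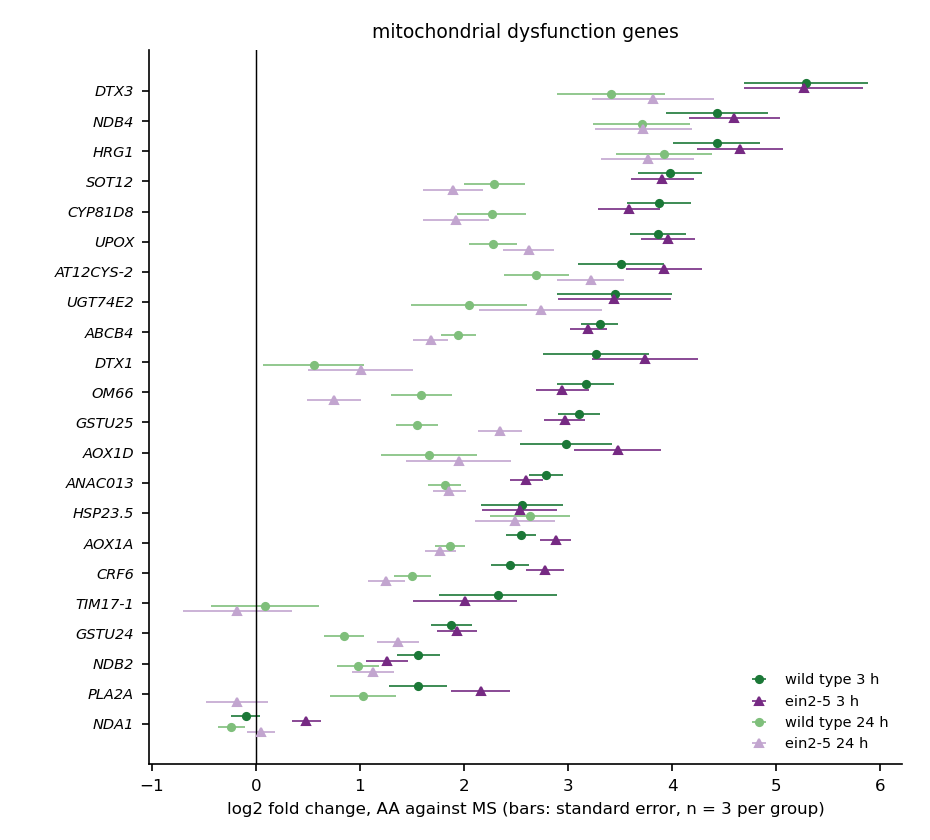
Log2 fold change of AA against MS (horizontal axis) for the mitochondrial dysfunction genes in wild type (circles) and ein2-5 (triangles) at 3 h and 24 h, with SE bars, n = 3 libraries per group. AOX1A stands at 2.55 in wild type and 2.88 in ein2-5 at 3 h.

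The AA by genotype interaction asked whether ein2-5 answered AA differently from wild type. At 3 h 15 genes passed, 6 above 0 and 9 below, against 1625 at an unadjusted p under 0.05, and DESeq2 called 60 (42 above, 18 below), a replicate block 8 and these libraries alone 5. GDPD2 (AT5G41080), a glycerophosphodiesterase of phosphate recycling, went from 11 ± 0.570 to 88.4 ± 12.2 CPM with AA in wild type and from 19.4 ± 3.02 to 69.5 ± 8.77 CPM in ein2-5 (-1.16 ± 0.19, adjusted p = 0.00744). GDH2 (AT5G07440), a mitochondrial glutamate dehydrogenase, went from 167 ± 10.4 to 439.9 ± 6.42 CPM and from 206 ± 8.87 to 324 ± 18 CPM (-0.74 ± 0.11, adjusted p = 0.00245). None of the mitochondrial markers passed: AOX1A stood at 0.33 ± 0.20 (adjusted p = 0.74), UPOX at 0.10 ± 0.38, NDB4 at 0.17 ± 0.79 and ANAC013 at -0.19 ± 0.22. The mitochondrial dysfunction list had a median of 0.03 with no member called (adjusted p = 0.368). Ethylene-responsive genes had a median of 0.03 and no member called (adjusted p = 0.311). Unadjusted p-values under 0.05 numbered 1 of 22 and 4 of 20, and DESeq2 called 0 of either. Without the deviating ein2-5 MS replicate 3, chosen after the data were seen, both lists passed above 0 (adjusted p = 4.01e-05 and 0.0434, or 0.35 and 0.328 with an estimated correlation). ERF1 stood at -1.41 ± 1.06. Photosynthesis genes (median 0.30, adjusted p = 2.11e-10) and core hypoxia genes (median 0.26, adjusted p = 3.17e-05) lay above 0, and sugar starvation genes below (median -0.29, adjusted p = 0.000191), each at adjusted p = 0.486 with an estimated correlation. That replicate lay below its group for photosynthesis (median -0.36) and sugar starvation genes (-0.33), and without it the adjusted p of photosynthesis, hypoxia and sugar genes was 7.26e-06, 4.01e-05 and 1.52e-07. No member of these 3 lists was called over all genes (14, 9 and 5 at an unadjusted p under 0.05, and 0 with DESeq2), and 7, 2 and 4 members were when adjusted over the list alone. The count at 3 h was 6, 9 and 3 without wild-type AA replicate 1, 2 and 3, 7 and 4 without wild-type MS replicate 2 and 3, 6 and 7 without ein2-5 AA replicate 1 and 3, and 4 without ein2-5 MS replicate 1.

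At 24 h 63 genes passed, 28 above 0 and 35 below, and 162 with DESeq2. PDC1, which AA raised in wild type, stood at 166 ± 19.5 CPM with AA and 139.9 ± 18.4 CPM with MS in ein2-5 (-1.30 ± 0.17, adjusted p = 9.51e-05), and SUS4 differed likewise (-1.18 ± 0.13, adjusted p = 1.74e-05). CYP81F2 (AT5G57220), a cytochrome P450 of indole glucosinolates, went from 7.14 ± 0.121 to 32.4 ± 2.97 CPM in wild type and from 29.2 ± 1.32 to 35.7 ± 3.74 CPM in ein2-5 (-1.89 ± 0.23, adjusted p = 5.07e-05). AT1G26240 changed less in ein2-5 (-3.64 ± 0.52, adjusted p = 0.000323, or -2.78 without ein2-5 MS replicate 1), and the aquaporin TIP2;3 (AT5G47450), which was lower with AA in wild type, was less so in ein2-5 (1.79 ± 0.29, adjusted p = 0.00158). Core hypoxia genes lay below 0 (3 of 27 called, 13 adjusted over the list alone, median -0.44, adjusted p = 1.81e-13, or 0.0883 with an estimated correlation). Abscisic acid and drought genes lay above 0 (2 of 17, 10 adjusted over the list alone, median 0.65, adjusted p = 3.62e-13, or 0.0883 with an estimated correlation). Jasmonate genes lay above 0 too (1 of 19, median 0.45, adjusted p = 0.000419, or 0.427 with an estimated correlation). The mitochondrial dysfunction list had no member called (3 at an unadjusted p under 0.05, 0 with DESeq2) and a median of 0.03 (adjusted p = 0.81). AOX1A stood at -0.09 ± 0.20, UPOX at 0.34 ± 0.33, OM66 at -0.84 ± 0.40 and ANAC013 at 0.04 ± 0.22, all with adjusted p-values of 0.505 or more. The count at 24 h was 34 and 41 without wild-type AA replicate 1 and 3, 36 and 32 without wild-type MS replicate 1 and 2, and 31 without ein2-5 AA replicate 2.

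Averaged over genotypes, AA changed 3974 genes at 3 h (2064 higher, 1910 lower, but 1814 and 2496 with upper-quartile factors) and 4966 at 24 h (2320 higher, 2646 lower). Over the genes called at 3 h, the mean signed response was 0.73 ± 0.02 in wild type and 0.75 ± 0.04 in ein2-5 on the log2 scale (SD over the 3 AA libraries), a difference of 0.03 ± 0.03 (SE, exact permutation p = 0.4, two-sided). Over those called at 24 h the difference was -0.03 ± 0.03 (exact permutation p = 0.5), and over the 657 genes that changed by at least 2-fold at 24 h it was -0.17 ± 0.06 (exact permutation p = 0.1), which is the smallest p that 3 libraries against 3 can give. Across all tested genes the AA changes of both genotypes correlated with Pearson's r = 0.696 and Spearman's rho = 0.461 at 3 h and 0.584 and 0.483 at 24 h, where genes are not independent replicates. Both genotypes called 1470 genes in the same direction at 3 h, against 137.5 expected of independent lists, and 2 in opposite directions, and at 24 h the numbers were 1437, 191.2 and 8.

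The AA by time interaction asked which AA changes differed between 24 h and 3 h. In wild type 1381 genes passed, 543 above 0 and 838 below. Iron deficiency genes lay above 0 in 6 of 7 cases, 7 adjusted over the list alone (median 3.92, adjusted p = 1.60e-16). BHLH100 stood at 5.98 ± 0.68 and BHLH38 at 5.56 ± 0.70. Core hypoxia genes lay above 0 in 17 of 27 (median 1.64, adjusted p = 8.15e-29), with 2 below 0, 3 adjusted over the list alone. HUP9 (6.00 ± 0.51), SUS4 (2.81 ± 0.14), SAD6 (2.79 ± 0.19) and PDC1 (2.43 ± 0.17) turned from lower with AA at 3 h to higher at 24 h by their means in CPM. Auxin-responsive genes lay below 0 in 8 of 9 cases (median -1.90, adjusted p = 8.04e-20). GH3.3 stood at -3.76 ± 0.20. Sugar starvation genes lay below 0 in 10 of 11, 11 adjusted over the list alone (median -1.40, adjusted p = 5.46e-24). BGLU30 stood at -3.83 ± 0.42. Mitochondrial dysfunction genes lay below 0 in 11 of 22 cases, 13 adjusted over the list alone (median -1.17, adjusted p = 3.95e-11, or 0.0897 with an estimated correlation). ABCB4 stood at -1.36 ± 0.24, UPOX at -1.59 ± 0.36, OM66 at -1.58 ± 0.40 and ANAC013 at -0.97 ± 0.22. AT1G13609 stood at 5.92 ± 0.68 and CHI-B at 0.65 ± 0.16.

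The calls of AOX1A (-0.68 ± 0.20, adjusted p = 0.0335) and CYP81D8 (-1.61 ± 0.44, adjusted p = 0.0218) in wild type were the least firm of these. That of AOX1A was lost without any 1 of AA replicates 2 and 3 at 3 h, AA replicates 2 and 3 at 24 h, MS replicates 2 and 3 at 3 h and MS replicates 1, 2 and 3 at 24 h (highest adjusted p = 0.0824). That of CYP81D8 was lost without MS replicate 2 or 3 at 3 h or MS replicate 1 or 2 at 24 h (highest adjusted p = 0.0703) and with DESeq2 (adjusted p = 0.0532).

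In ein2-5 the AA by time interaction held 2224 genes, 915 above 0 and 1309 below. Iron deficiency genes lay above 0 in 5 of 7 cases, 6 adjusted over the list alone (median 2.48, adjusted p = 3.72e-08, or 0.0532 with an estimated correlation). BHLH100 stood at 6.11 ± 0.65 and BHLH38 at 4.15 ± 0.61. Core hypoxia genes were above 0 in 13 of 27 and below in 3, the former 17 adjusted over the list alone (median 0.68, adjusted p = 2.63e-08, or 0.133 with an estimated correlation). HUP9 stood at 3.06 ± 0.37, HRA1 at 1.62 ± 0.19 and SUS4 at 1.35 ± 0.13. Below 0 were auxin-responsive genes in 7 of 9 cases (median -1.84, adjusted p = 2.16e-14), sugar starvation genes in 8 of 11, 11 adjusted over the list alone (median -0.94, adjusted p = 1.70e-12), and mitochondrial dysfunction genes in 11 of 22 (median -1.22, adjusted p = 2.12e-10, adjusted p = 0.133 with an estimated correlation). Examples were GH3.3 (-3.76 ± 0.20), AT4G28460 (-5.70 ± 0.81), WRKY30 (AT5G24110, -3.37 ± 0.59), OM66 (-2.20 ± 0.36), ABCB4 (-1.51 ± 0.23), CYP81D8 (-1.66 ± 0.42), UPOX (-1.34 ± 0.35) and AOX1A (-1.11 ± 0.20), while CHI-B lay above 0 (0.89 ± 0.16). The call of ANAC013 (-0.74 ± 0.22, adjusted p = 0.0269) was lost without any 1 of AA replicate 1 and MS replicates 1 and 2 at 3 h and AA replicates 2 and 3 and MS replicate 3 at 24 h (highest adjusted p = 0.101) and in a fit of these libraries alone (adjusted p = 0.0621).

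**Figure D4:**
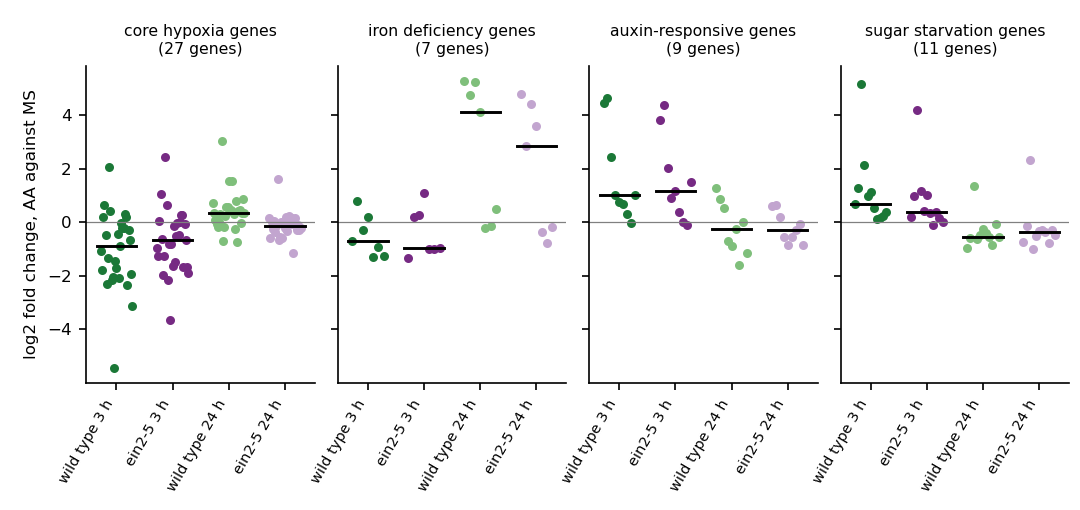
Log2 fold change of AA against MS (vertical axis) in each genotype and time, with a panel per gene list, a point per gene and a bar at the median of the list. The core hypoxia median is -0.89 in wild type at 3 h and 0.33 at 24 h.

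The genotypes were compared in each condition to see what loss of EIN2 changes. Untreated ein2-5 had less transcript of ethylene-responsive genes, 9 of 20 lower and 0 higher, 14 lower adjusted over the list alone (median -0.74, adjusted p = 1.86e-17). EBF2, the F-box protein that removes EIN3, went from 72.5 ± 7.68 CPM in wild type to 26.3 ± 4.88 CPM (-1.46 ± 0.14, adjusted p = 3.46e-08). The receptor ETR2 (AT3G23150) differed by -1.41 ± 0.16, the receptor ERS1 (AT2G40940) by -0.82 ± 0.11, and ARL (AT2G44080), a growth gene of the ARGOS family, by -1.40 ± 0.14. EIN2 stood at -1.31 ± 0.09 (adjusted p = 3.72e-11), EIN3 (AT3G20770), the transcription factor of ethylene responses, at -1.71 ± 0.08 and its homologue EIL1 (AT2G27050) at 2.49 ± 0.15. The perception and signalling list includes EIN2 and overlaps the ethylene-responsive one. Of its genes 2 of 13 were higher and 6 lower, the latter 8 adjusted over the list alone (adjusted p = 5.34e-07). Senescence genes were lower in 4 of 11 cases (adjusted p = 8.04e-05, or 0.0544 with an estimated correlation). The senescence factors NAP (AT1G69490) stood at -1.76 ± 0.17 and ORE1 (AT5G39610) at -1.52 ± 0.28. Sugar starvation genes were lower in 4 of 11, 6 adjusted over the list alone (adjusted p = 1.60e-06, or 0.086 with an estimated correlation). TPS11 stood at -0.81 ± 0.11. Core hypoxia genes were higher in 5 and lower in 1 of 27, the former 14 adjusted over the list alone (adjusted p = 9.36e-07, or 0.267 with an estimated correlation). Mitochondrial dysfunction genes were lower in 2 of 22, 3 adjusted over the list alone (adjusted p = 0.0363, or 0.778 with an estimated correlation). ERF1 (-0.98 ± 0.84), PDF1.2A (-1.12 ± 0.46), CHI-B (0.11 ± 0.11) and HEL (-0.47 ± 0.16) had adjusted p-values of 0.107 or more, though HEL passed without ein2-5 replicate 2 (adjusted p = 0.00965).

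The test called 921 genes between the untreated genotypes, 321 higher and 600 lower in ein2-5, 207 of them by at least 2-fold, and 588 without wild-type replicate 1. AT1G75945 (6.64 ± 0.50), the hydrolase AT4G14290 (3.79 ± 0.14) and MRN1 (3.17 ± 0.47) were far above wild type. The ethylene response factor RAP2.6 (AT1G43160, -3.80 ± 0.44), PRP1 (-2.90 ± 0.26), the extensin EXT12 (AT4G13390, -2.87 ± 0.19) and SAG13 (AT2G29350), an alcohol dehydrogenase (-2.03 ± 0.42), were far below. In all 5 conditions 89 genes were higher and 98 lower in ein2-5.

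With MS at 3 h ein2-5 had lower ethylene-responsive transcripts in 12 of 20 cases (median -1.15, adjusted p = 2.07e-14): ARGOS (AT3G59900), an ethylene-induced growth regulator, stood at -2.92 ± 0.34, ARL at -2.16 ± 0.14, ETR2 at -1.92 ± 0.16 and EBF2 at -1.40 ± 0.14 (adjusted p-values of 5.14e-07 or less). Perception and signalling genes were lower in 8 and higher in 2 of 13 (adjusted p = 3.35e-07). EIN2 stood at -1.31 ± 0.09, EIN3 at -1.42 ± 0.08 and EIL1 at 2.67 ± 0.15. The ethylene-forming oxidase ACO5 (AT1G77330, -1.12 ± 0.12) was lower in ein2-5, and the synthases ACS7 (AT4G26200, 2.02 ± 0.36, or 1.38 without ein2-5 replicate 3) and ACS11 (AT4G08040, 1.81 ± 0.35) higher. Salicylic acid genes were higher in 7 of 16, 10 adjusted over the list alone (adjusted p = 5.15e-06, or 0.179 with an estimated correlation). FMO1 (AT1G19250) stood at 1.64 ± 0.34 and EDS5 (AT4G39030) at 1.13 ± 0.15. Nuclear photosynthesis genes were lower in 13 of 20, 20 adjusted over the list alone (adjusted p = 6.42e-10, adjusted p = 0.308 with an estimated correlation), but the deviating ein2-5 replicate 3 lay below its group for them (median -0.36), and without it the adjusted p was 5.16e-06. Of all genes 2215 passed (1247 higher, 968 lower), and 1260, 1280 and 1289 did without wild-type replicate 2, wild-type replicate 3 and the deviating ein2-5 replicate 3, and 771 with these libraries alone. RLE factors (1112 higher, 1135 lower), 1 CPM in 3 libraries (1124, 1152) and DESeq2 (1259, 1295) turned the balance. The peroxidases AT5G19890 (-5.97 ± 0.59) and AT1G49570 (-4.49 ± 0.36), RAP2.6 (-4.69 ± 0.49), the potassium transporter HAK5 (AT4G13420, -2.53 ± 0.24) and BEE3 (AT1G73830), a factor of brassinosteroid responses (-2.52 ± 0.13), were far below wild type. AT1G75945 (6.30 ± 0.52), MRN1 (4.46 ± 0.57) and AT4G14290 (4.45 ± 0.14) were far above. PDF1.2A stood at -1.43 ± 0.47 (adjusted p = 0.0457), a call lost without replicate 1 or 3 of either genotype (highest adjusted p = 0.16) and with replicate number as a block (adjusted p = 0.054) or these libraries alone (adjusted p = 0.0944). ERF1 (-1.38 ± 0.75), CHI-B (0.17 ± 0.11) and HEL (-0.33 ± 0.16) had adjusted p-values of 0.215 or more.

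With MS at 24 h, ethylene-responsive genes were lower in ein2-5 in 8 of 20 cases, 10 adjusted over the list alone (median -0.52, adjusted p = 4.67e-09). EBF2 stood at -1.82 ± 0.15, ARL at -1.80 ± 0.14 and ETR2 at -1.74 ± 0.16. Perception and signalling genes were lower in 7 and higher in 2 of 13, the former 8 adjusted over the list alone (adjusted p = 3.70e-08). EIN2 stood at -1.40 ± 0.09, EIN3 at -1.49 ± 0.08 and EIL1 at 1.98 ± 0.14. Core hypoxia genes were higher in 19 of 27 cases and lower in 1, the former 24 adjusted over the list alone (median 0.68, adjusted p = 2.12e-16). SUS4 stood at 1.31 ± 0.10, PDC1 at 1.29 ± 0.12 and LBD41 (AT3G02550), a hypoxia-induced factor, at 1.11 ± 0.12. Jasmonate genes were higher in 11 of 19, 15 adjusted over the list alone (adjusted p = 6.49e-10). JAZ7 (AT2G34600), a repressor of jasmonate signalling, stood at 2.96 ± 0.51, LOX2 (AT3G45140), a lipoxygenase, at 1.55 ± 0.19 and VSP1 (AT5G24780) at 1.37 ± 0.30. Sugar starvation genes were higher in 8 of 11, with 2 lower adjusted over the list alone (adjusted p = 1.40e-08), as in ASN1 (1.28 ± 0.13) and TPS11 (1.05 ± 0.12). Salicylic acid genes were higher in 7 of 16, 10 adjusted over the list alone (adjusted p = 1.71e-07, adjusted p = 0.0677 with an estimated correlation), with the regulators CBP60G (AT5G26920, 1.50 ± 0.21) and SARD1 (AT1G73805, 1.50 ± 0.25). The synthases ACS8 (AT4G37770, 2.81 ± 0.46) and ACS11 (2.42 ± 0.32) were higher too. Of all genes 2420 passed (1432 higher, 988 lower), 1592 without wild-type replicate 1, and AT4G33720 (-6.57 ± 0.72), AT5G19890 (-5.34 ± 0.56), RAP2.6 (-4.17 ± 0.44) and EXT12 (-3.21 ± 0.20) were far below wild type. ERF1 (-1.17 ± 0.83), PDF1.2A (-0.93 ± 0.38) and CHI-B (-0.05 ± 0.11) had adjusted p-values of 0.122 or more.

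With AA at 3 h the ethylene-responsive genes of ein2-5 were lower in 11 of 20 cases and higher in 1 (median -0.62, adjusted p = 1.99e-11). ARGOS stood at -2.65 ± 0.31, ARL at -2.19 ± 0.14, ETR2 at -2.04 ± 0.16 and EBF2 at -1.58 ± 0.14. Perception and signalling genes were lower in 8 and higher in 2 of 13 (adjusted p = 2.62e-10). EIN2 stood at -1.43 ± 0.09, EIN3 at -1.72 ± 0.08 and EIL1 at 2.45 ± 0.15. Abscisic acid and drought genes were higher in 12 of 17, 13 adjusted over the list alone (median 0.79, adjusted p = 5.62e-12, or 0.054 with an estimated correlation). NCED3 (AT3G14440), the rate-limiting enzyme of abscisic acid synthesis, stood at 1.47 ± 0.22, COR15A at 1.41 ± 0.22 and RD29A (AT5G52310) at 0.91 ± 0.12. Mitochondrial dysfunction genes were higher in 6 of 22, 12 adjusted over the list alone (median 0.57, adjusted p = 2.35e-06, adjusted p = 0.261 with an estimated correlation). The test called 1662 genes (1034 higher, 628 lower), 1073 without ein2-5 replicate 3, and ATSDI1 (AT5G48850), a sulphur deficiency gene (3.17 ± 0.21), NUDT24 (4.52 ± 0.71), AT5G40590 (-3.11 ± 0.39) and HAK5 (-2.32 ± 0.23) differed strongly. The calls of ERF1 (-2.79 ± 0.71, adjusted p = 0.0116) and PDF1.2A (-1.82 ± 0.43, adjusted p = 0.00594) were lost, that of ERF1 without wild-type replicate 2 or ein2-5 replicate 1 or 2 (highest adjusted p = 0.0793) and that of PDF1.2A without wild-type replicate 2 (adjusted p = 0.0648), and CHI-B stood at 0.04 ± 0.11.

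After 24 h of AA the ethylene-responsive genes were lower in ein2-5 in 10 of 20 cases, 12 adjusted over the list alone (median -0.77, adjusted p = 2.25e-12). ARL stood at -2.06 ± 0.14, ETR2 at -1.52 ± 0.16 and EBF2 at -1.30 ± 0.14. The perception and signalling list had 7 of 13 lower and 2 higher (adjusted p = 3.89e-05, or 0.05 with an estimated correlation). EIN2 stood at -1.24 ± 0.09, EIN3 at -1.65 ± 0.08, EIL1 at 2.31 ± 0.15 and EBF1 (AT2G25490), a homologue of EBF2, at 0.86 ± 0.07. Jasmonate genes were higher in 15 of 19, 19 adjusted over the list alone (median 1.02, adjusted p = 2.11e-20), with the storage proteins VSP1 (2.29 ± 0.32, or 1.60 without ein2-5 replicate 1) and VSP2 (AT5G24770, 1.86 ± 0.25), LOX2 (1.77 ± 0.19) and the repressor JAZ9 (AT1G70700, 1.24 ± 0.11). Sugar starvation genes were higher in 8 of 11 (median 0.57, adjusted p = 2.91e-11), as in ASN1 (1.54 ± 0.13). Abscisic acid and drought genes were higher in 9 and lower in 1 of 17, the former 11 adjusted over the list alone (adjusted p = 1.20e-05, or 0.255 with an estimated correlation). The phosphatase HAI1 (AT5G59220) stood at 2.19 ± 0.33 (1.56 without ein2-5 replicate 2) and COR15A at 1.85 ± 0.24. No mitochondrial dysfunction gene passed (2 at an unadjusted p under 0.05, 0 with DESeq2, median -0.21, adjusted p = 0.226). Of all genes 2107 passed (1170 higher, 937 lower, but 1006 and 1146 with upper-quartile factors), 1340 and 1371 without ein2-5 replicate 2 and wild-type replicate 1, and AT1G75945 (8.11 ± 0.64), AT4G14290 (3.94 ± 0.14), AT5G50335 (-5.22 ± 0.56) and EXT12 (-3.83 ± 0.25) differed strongly. The call of PDF1.2A (-1.41 ± 0.40, adjusted p = 0.0195) was lost without wild-type replicate 1 or 3 or ein2-5 replicate 1 or 2 (highest adjusted p = 0.0795), and ERF1 (-0.58 ± 0.88) and CHI-B (0.06 ± 0.11) had adjusted p-values of 0.769 or more.

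**Figure D5:**
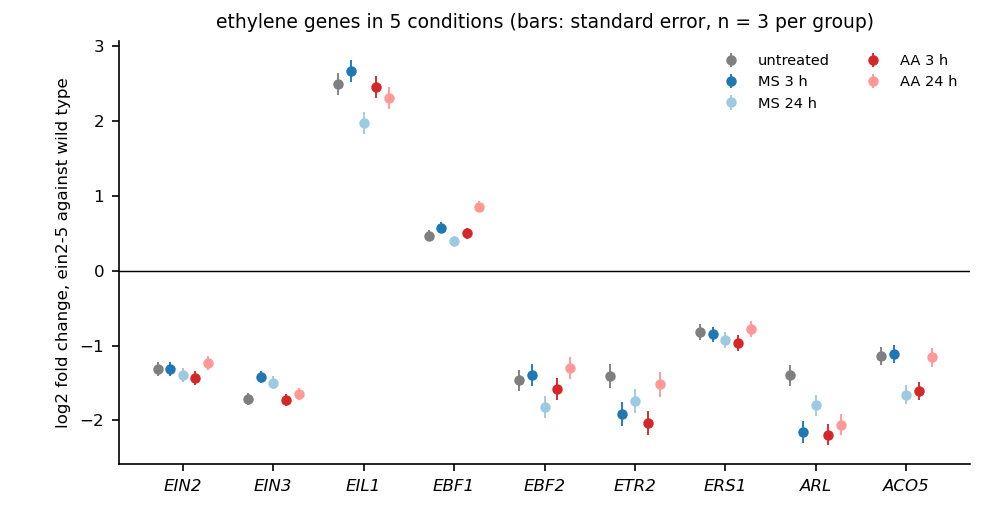
Log2 fold change of ein2-5 against wild type (vertical axis) for genes of ethylene synthesis and signalling in the 5 conditions, with SE bars, n = 3 libraries per group. EIL1 stands between 1.98 and 2.67 and EIN3 between -1.72 and -1.42.

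MS was compared with untreated seedlings to see what covering alone changes, although elapsed time, hour of the day and the batch named in the labels change with it and cannot be told apart from it. In wild type at 3 h clock genes changed in both directions, 8 of 11 higher and 3 lower, with a median of 0.71, a mean of 0.12 and no call as a list (adjusted p = 0.107), and fry's test pointed down. The morning factors LHY (AT1G01060, -5.48 ± 0.14, adjusted p = 4.54e-23), RVE8 (AT3G09600, -3.02 ± 0.11) and CCA1 (AT2G46830, -2.77 ± 0.08) were lower and the pseudo-response regulator PRR5 (AT5G24470) higher (4.61 ± 0.22). Sugar starvation genes fell in 10 of 11 cases (median -1.75, adjusted p = 8.86e-13). TPS11 stood at -2.47 ± 0.12, TPS8 (AT1G70290) at -2.04 ± 0.12 and DIN10 at -2.01 ± 0.12. Core hypoxia genes were higher in 11 and lower in 3 of 27 (adjusted p = 0.0531). The fermentation enzymes ADH1 (AT1G77120) stood at 1.03 ± 0.19 and PDC1 at 0.80 ± 0.12, the hypoxia factor HRE1 (AT1G72360) at 0.74 ± 0.12 and the oxygen sensor PCO1 (AT5G15120) at 0.14 ± 0.10 (adjusted p = 0.324). The catalases CAT1 (AT1G20630, 2.03 ± 0.14) and CAT3 (1.46 ± 0.12) rose and CAT2 (AT4G35090) fell (-1.81 ± 0.09). In all 7055 genes passed, 3361 higher and 3694 lower (but 3951 and 3200 with upper-quartile factors and 3582 and 3504 with 1 CPM in 3 libraries), with AT5G62360 (6.73 ± 0.32), AT1G56300 (5.73 ± 0.26), COR15B (AT2G42530, 4.49 ± 0.29), BMY3 (AT5G18670), a beta-amylase (-4.18 ± 0.10), and AT1G26790, a Dof factor (-7.40 ± 0.42), among the strong changes.

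In ein2-5 at 3 h of MS clock genes again went both ways, 8 of 11 higher and 3 lower (median 0.71, adjusted p = 0.116, with fry's test pointing down). LHY stood at -5.08 ± 0.13, RVE8 at -2.83 ± 0.11, CCA1 at -2.80 ± 0.08, PRR5 at 4.39 ± 0.22 and FKF1 (AT1G68050), a light-sensing F-box protein, at 5.63 ± 0.58. Sugar starvation genes fell in 10 of 11 cases, 11 adjusted over the list alone (median -1.39, adjusted p = 4.49e-11). TPS11 stood at -2.22 ± 0.12. Touch and early stress regulators rose in 10 of 14, 11 adjusted over the list alone (median 1.29, adjusted p = 3.13e-06, or 0.406 with an estimated correlation). ZAT10 (AT1G27730) stood at 2.95 ± 0.27 and WRKY33 (AT2G38470) at 1.74 ± 0.16. Jasmonate genes rose in 13 and fell in 1 of 19, the former 15 adjusted over the list alone (adjusted p = 3.32e-05, or 0.443 with an estimated correlation). The repressor JAZ1 (AT1G19180) stood at 2.07 ± 0.22. The deviating MS replicate 3 lay above its group for touch (median 0.53) and jasmonate genes (0.38), and without it the adjusted p of each was 7e-05. Core hypoxia genes went both ways, 8 higher and 5 lower of 27, 9 and 6 adjusted over the list alone (adjusted p = 0.757). PDC1 stood at 0.50 ± 0.12, ADH1 at 0.31 ± 0.19 (adjusted p = 0.239) and HRE1 at 0.04 ± 0.12 (adjusted p = 0.852). PCO1 stood at -0.27 ± 0.10 (adjusted p = 0.0374), a call lost without MS replicate 1 or 3 or untreated replicate 2 or 3 (highest adjusted p = 0.217) and with these libraries alone (adjusted p = 0.115), and ADH1 passed without untreated replicate 2 (adjusted p = 0.0192). The catalases stood at 1.69 ± 0.14 for CAT1, 1.79 ± 0.12 for CAT3 and -1.68 ± 0.08 for CAT2, and 6733 genes passed in all (3674 higher, 3059 lower).

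After 24 h of MS in wild type sugar starvation genes were lower in 9 of 11 cases (median -1.36, adjusted p = 8.66e-15). DIN10 stood at -1.87 ± 0.12, TPS11 at -1.81 ± 0.12 and TPS9 (AT1G23870) at -1.25 ± 0.09. Iron deficiency genes were lower in 6 of 7 (median -1.63, adjusted p = 2.78e-05, or 0.232 with an estimated correlation). BHLH101 stood at -3.33 ± 0.38 and IRT1 at -1.49 ± 0.21. Core hypoxia genes were lower in 12 and higher in 2 of 27, the latter 3 adjusted over the list alone (adjusted p = 0.00101, adjusted p = 0.457 with an estimated correlation). PDC1 stood at -0.61 ± 0.12. ADH1 (-0.13 ± 0.19), HRE1 (-0.26 ± 0.12) and PCO1 (-0.21 ± 0.10) had adjusted p-values of 0.143 or more, though HRE1 passed without untreated replicate 1 (adjusted p = 0.0436). LHY (-1.97 ± 0.11) and CCA1 (-0.94 ± 0.08) were lower and PRR7 (AT5G02810), a repressor of both, higher (0.99 ± 0.08). The small heat shock protein HSP17.6A (AT5G12030) rose by 3.98 ± 0.61. Of all genes 4222 passed (1867 higher, 2355 lower, but 2188 and 2025 with upper-quartile factors), with AT1G70820 (3.00 ± 0.17), AT3G44450 (2.80 ± 0.31), BT2 (AT3G48360), a scaffold protein (-3.36 ± 0.16), GDPD2 (-3.27 ± 0.14) and AT1G50040 (-4.31 ± 0.29) among the strong changes.

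In ein2-5 at 24 h of MS defence transcripts were higher than in untreated seedlings: salicylic acid genes in 10 of 16 cases, 12 adjusted over the list alone (median 1.15, adjusted p = 3.00e-08, adjusted p = 0.112 with an estimated correlation). ALD1 (AT2G13810) stood at 2.21 ± 0.33 and CBP60G at 1.53 ± 0.21. Jasmonate genes were higher in 12 of 19, 14 adjusted over the list alone (adjusted p = 6.95e-09, or 0.112 with an estimated correlation). VSP1 stood at 1.88 ± 0.31 and AOC2 (AT3G25770) at 1.33 ± 0.14. Touch and early stress regulators were higher in 7 of 14, 11 adjusted over the list alone (adjusted p = 5.74e-08, or 0.112 with an estimated correlation). The defensin PDF1.2B (AT2G26020) rose by 4.30 ± 0.60. Sugar starvation genes were lower in 3 and higher in 1 of 11, the former 6 adjusted over the list alone (adjusted p = 0.014, or 0.484 with an estimated correlation). Core hypoxia genes were higher in 3 of 27, with a median of -0.06, a mean of 0.04 and a test that pointed up without passing (adjusted p = 0.649). ADH1 (0.13 ± 0.19), PDC1 (0.05 ± 0.12), HRE1 (-0.21 ± 0.12) and PCO1 (-0.06 ± 0.10) had adjusted p-values of 0.268 or more. LHY stood at -1.90 ± 0.11, CCA1 at -1.05 ± 0.08 and PRR7 at 1.07 ± 0.08. Of all genes 3191 passed (1794 higher, 1397 lower, and 2116 with these libraries alone), and AT5G41280 (3.41 ± 0.39), WRKY38 (AT5G22570, 3.13 ± 0.53), CML41 (AT3G50770, 3.11 ± 0.47), the response regulator ARR15 (AT1G74890, -2.53 ± 0.26) and AT1G26790 (-2.73 ± 0.26) changed strongly.

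The MS by genotype interaction asked where the change from untreated to MS differed between the genotypes. At 3 h 313 genes passed, 252 above 0 and 61 below, 536 with DESeq2 (358 above, 178 below) and 87 with these libraries alone. TCH4 (AT5G57560), a touch-induced cell wall enzyme, went from 189 ± 27 to 29.2 ± 5.71 CPM in wild type and from 59.9 ± 11.3 to 65 ± 51.3 CPM in ein2-5 (2.81 ± 0.48, adjusted p = 0.00158). PHI-1 (AT1G35140) stood at 3.35 ± 0.50, TAT3 (AT2G24850), a wound-induced aminotransferase, at 5.41 ± 1.04, CBP60G at 1.46 ± 0.29 and OEP6 (AT3G63160) at -1.18 ± 0.20. Salicylic acid genes lay above 0 in 4 of 16 cases, 9 adjusted over the list alone (adjusted p = 2.19e-07, or 0.246 with an estimated correlation). Touch and early stress regulators lay above 0 in 2 of 14, 4 adjusted over the list alone (adjusted p = 1.47e-06, adjusted p = 0.246 with an estimated correlation), and mitochondrial dysfunction genes in 2 of 22, 8 adjusted over the list alone (adjusted p = 3.59e-06, adjusted p = 0.377 with an estimated correlation). Without the deviating ein2-5 MS replicate 3 TCH4 stood at 1.93 (adjusted p = 0.00338), PHI-1 at 2.51 and TAT3 at 4.78. That replicate lay above its group by a median of 0.85 for mitochondrial dysfunction and 0.53 for touch genes, and without it the adjusted p of these lists was 0.000913 and 2.66e-05. HRE1 stood at -0.70 ± 0.17 (adjusted p = 0.0272), a call lost without wild-type MS replicate 2 or 3, untreated wild-type replicate 1 or 2, ein2-5 MS replicate 2 or 3, or untreated ein2-5 replicate 1 (highest adjusted p = 0.0982) and with these libraries alone (adjusted p = 0.116). The count was 148 and 161 without wild-type MS replicate 3 and 2, 181 without ein2-5 MS replicate 3, 207 without untreated ein2-5 replicate 1 and 543 without ein2-5 MS replicate 1.

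At 24 h the MS by genotype interaction held 852 genes, 679 above 0 and 173 below. Sugar starvation genes lay above 0 in 9 of 11 cases (median 1.04, adjusted p = 1.64e-14): TPS11 went from 221 ± 7.86 to 62.9 ± 5.08 CPM in wild type and from 126 ± 17.3 to 130.2 ± 9.19 CPM in ein2-5 (1.86 ± 0.16, adjusted p = 1.05e-08). TPS8 stood at 1.80 ± 0.16 and DIN10 at 1.44 ± 0.17. BT2 went from 295 ± 10.7 to 28.6 ± 6.42 CPM in wild type and from 168 ± 37.4 to 169 ± 6.42 CPM in ein2-5 (3.37 ± 0.21, adjusted p = 8.25e-12). Jasmonate genes lay above 0 in 6 of 19 cases, 8 adjusted over the list alone (adjusted p = 8.49e-08, or 0.15 with an estimated correlation). JAZ7 stood at 4.09 ± 0.68. Salicylic acid genes lay above 0 in 3 of 16, 6 adjusted over the list alone (adjusted p = 5.89e-08, or 0.138 with an estimated correlation). Touch and early stress regulators lay above 0 in 5 of 14, 8 above and 1 below adjusted over the list alone (adjusted p = 2.56e-07, or 0.15 with an estimated correlation). TPS04 (AT1G61120), a terpene synthase, stood at 5.74 ± 1.33, ACS11 at 3.41 ± 0.45 and AT2G15020 at -1.67 ± 0.18. The call of PDC1 (0.66 ± 0.17, adjusted p = 0.0192) was lost without untreated wild-type replicate 2, ein2-5 MS replicate 2 or untreated ein2-5 replicate 3 (highest adjusted p = 0.0796).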

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

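Tests of adjacent genes and of chromosomes were chosen only after the results were seen. The values of the first paragraphs are listed because an interaction test passed: AA or MS with genotype, or AA with time.

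With AA at 3 h the genotypes differed in their change in 15 genes, among them GDPD2 (-1.16) and GDH2 (-0.74). At 24 h they differed in 63, with TIP2;3 at 1.79, AT1G26240 at -3.64, CYP81F2 at -1.89, PDC1 at -1.30 and SUS4 at -1.18. With MS at 3 h the change from untreated differed in 313 genes, with TAT3 at 5.41, PHI-1 at 3.35, TCH4 at 2.81, OEP6 at -1.18, CBP60G at 1.46 and HRE1 at -0.70. At 24 h it differed in 852, with TPS04 at 5.74, ACS11 at 3.41, BT2 at 3.37, AT2G15020 at -1.67, TPS8 at 1.80, TPS11 at 1.86, DIN10 at 1.44, JAZ7 at 4.09, PDC1 at 0.66 and sugar starvation genes at a median of 1.04.

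The AA change differed between 24 h and 3 h in 1381 genes in wild type. BHLH100 stood at 5.98, BHLH38 at 5.56, AT1G13609 at 5.92, HUP9 at 6.00, SUS4 at 2.81, SAD6 at 2.79, PDC1 at 2.43 and CHI-B at 0.65. Below 0 were GH3.3 (-3.76), BGLU30 (-3.83), ABCB4 (-1.36), UPOX (-1.59), ANAC013 (-0.97), AOX1A (-0.68), OM66 (-1.58) and CYP81D8 (-1.61). List medians were 1.64 for core hypoxia, 3.92 for iron deficiency, -1.90 for auxin-responsive and -1.40 for sugar starvation genes. In ein2-5 the times differed in 2224 genes, with BHLH100 at 6.11, BHLH38 at 4.15, SUS4 at 1.35, HRA1 at 1.62, HUP9 at 3.06 and CHI-B at 0.89. GH3.3 (-3.76), WRKY30 (-3.37), AT4G28460 (-5.70), ABCB4 (-1.51), OM66 (-2.20), AOX1A (-1.11), UPOX (-1.34), CYP81D8 (-1.66) and ANAC013 (-0.74) lay below 0, as did auxin-responsive (median -1.84) and sugar starvation genes (-0.94). Libraries without which a call was lost are named in the report.

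Libraries were also split in other ways into groups of the same sizes. Splits of 6 libraries number only 10, too few for a share under 0.05, and in each such comparison 1 split, the real one, gave as many genes. For AA against MS the counts (and the highest of the other splits) were 2125 (0) in wild type and 2730 (1) in ein2-5 at 3 h, and 2760 (0) and 2945 (1) at 24 h. Between the genotypes they were 921 (7) untreated, 2215 (2) and 2420 (0) with MS and 1662 (0) and 2107 (0) with AA. For MS against untreated they were 7055 (0) and 6733 (15) at 3 h and 4222 (0) and 3191 (2) at 24 h. For the AA effect averaged over genotypes 1 of 100 splits, the real one, gave as many, so chance was excluded, with 3974 (1700) genes at 3 h and 4966 (2087) at 24 h.

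For interactions such splits can neither exclude nor show chance, as genotype or time differences enter them. As many genes came from 12 and 15 of 100 splits for AA by genotype (15 genes, highest other 1488, and 63, highest other 1482). They came from 16 and 6 for AA by time in wild type and ein2-5 (1381, highest other 4181, and 2224, highest other 4039), and from 6 and 7 for MS by genotype (313, highest other 1104, and 852, highest other 1168). The median of the other splits was 0 in each. A split that exchanges genotypes, or times, under 1 treatment only turns their difference into an interaction.

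GPT2 (AT1G61800), a glucose phosphate transporter of plastids, stood at 81.9 CPM in replicate 3 of ein2-5 with MS at 3 h and at 10.1 and 12.3 CPM in the other libraries of its group, and mitochondrial dysfunction genes lay higher by a median of 0.85 on the log2 scale. A mixture with material of AA-treated seedlings would give the same share over genes that AA raises and genes that AA lowers. The shares were 6.93% (95% bootstrap interval 5.36 to 9.88) over 374 genes and -7.4% (-13.6 to 1.25) over 100 genes, which argues against it. A different share of root and shoot tissue cannot be told apart, since root markers had a median of -0.062 and photosynthesis genes one of -0.358, which meets neither bound set for it. No biological explanation was tested.

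Differences of ein2-5 could stem from variants linked to EIN2 on chromosome 5 rather than from EIN2. Of the 200 tested genes nearest to EIN2, 1.5% differed in untreated seedlings against 4.4% of the others. The odds ratio of 0.332 (95% interval 0.068 to 0.989) argues against a linked block of that size in that condition. In the other conditions ratios of 1.21 to 1.295 (intervals within 0.724 to 1.99) leave it open. Of the genes that differ the same way in all 5 conditions, 31.2% lie on chromosome 5, against 23.4% of tested genes (odds ratio 1.49, 95% interval 1.07 to 2.04, Fisher's exact p = 0.0148, or 0.074 by Holm's method over the 5 chromosomes, with adjacent genes counted as independent). The ratio lay under the 1.5 set for it, so gathering there and variants on it stay open. Those genes formed 15 adjacent pairs, against a median of 1 and at most 6 in 10000 random placements that ignore shared reads (permutation p = 1e-04, the smallest these can give), 11 of them on chromosome 5. Loss of EIN2 itself stays open as the biological explanation.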

How the results depend on the processing

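Alternatives were chosen before the data were examined. List tests without replicate 3 of ein2-5 with MS at 3 h and the hypoxia list against untreated seedlings were added after the results were seen. Counts were within 1.5 times of those reported with RLE factors, upper-quartile factors, no count filter, a minimum of 1 CPM in 3 libraries and organelle genes left out. Which direction held more genes depended on scaling or filter in some comparisons. Those that turned were AA in ein2-5 at 3 h, its average at 3 h, MS in wild type, the genotypes with MS at 3 h and AA at 24 h, and the near-even AA in wild type at 24 h and AA by genotype at 3 h, with values given in the report. No gene or list result changed direction among those called in either fit, and results that passed under neither setting were taken as unchanged. Of 364 calls of named genes, RLE factors, no count filter and organelle genes left out each kept 364. Upper-quartile factors, the replicate block and DESeq2 each kept 363, and the compared libraries alone 360. Leaving out 1 library at a time kept 2448 of 2502, but the naming rule let only fixed genes lose a call. Of the 95 list calls described, a selection, 46 were kept with an estimated correlation, 86 with fry and 95 with the replicate block. All 25 of them that involve ein2-5 with MS at 3 h were kept without its replicate 3, and 2 more passed. In simulated data 21.2% of interactions of 1.5-fold were recovered, and what depth alone limits was not tested. Except where fewer libraries or a stricter threshold leave fewer calls by construction, the cause was not tested.

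At an adjusted p under 0.01, which leaves fewer genes by construction, counts fell by over 1.5 times for most comparisons. AA against MS gave 1392 genes in wild type and 1717 in ein2-5 at 3 h, and 1524 and 1659 at 24 h, the AA effect averaged over genotypes at 24 h 3180, the AA by genotype interaction 3 and 24, and the AA by time interaction 772 in wild type and 1166 in ein2-5. The genotype comparison gave 460 genes untreated, 1094 and 1331 with MS and 893 and 1168 with AA at 3 h and 24 h, MS against untreated at 24 h 2614 in wild type and 1901 in ein2-5, and the MS by genotype interaction 109 and 463. DESeq2 gave 60 and 162 genes for the AA by genotype interaction and 536 for the MS by genotype interaction at 3 h. With fits of the compared libraries alone there were 1728 genes for AA in ein2-5 at 3 h, 5 for the AA by genotype interaction at 3 h, 771 for the genotypes with MS at 3 h, 2116 for MS in ein2-5 at 24 h and 87 for the MS by genotype interaction at 3 h. The replicate block gave 8 genes for the AA by genotype interaction at 3 h. The difference in response size at 24 h was -0.173 over genes of at least 2-fold, and Pearson's r between the genotypes was 0.829 at 3 h and 0.754 at 24 h over genes of at least 5 CPM.

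Without 1 library, counts ranged from 1949 to 2761 for AA in ein2-5 at 24 h, from 3 to 18 and from 31 to 69 for the AA by genotype interaction at 3 h and 24 h, and from 148 to 543 for the MS by genotype interaction at 3 h. Between the genotypes they ranged from 588 to 745 untreated, from 1260 to 2380 and from 1592 to 2168 with MS, and from 1073 to 1286 and from 1340 to 1893 with AA.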

Other observations

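MRN1 and 5 other triterpene genes, side by side with it or with THAS1 (AT5G48010) on chromosome 5, were higher in ein2-5. They were picked after the results were seen, from adjacent genes that differ the same way in all 5 conditions, so neighbours outside that choice were not counted and the clusters were not tested as lists. Tests of adjacent genes and of hypoxia genes against untreated seedlings were also chosen then. In the marneral cluster MRN1 stood at 3.17 ± 0.47 untreated and 4.47 ± 0.59 with MS at 24 h, CYP71A16 (AT5G42590) at 1.79 ± 0.16 and 2.27 ± 0.16, and CYP705A12 (AT5G42580) at 1.76 ± 0.35 and 2.92 ± 0.38. In the thalianol cluster THAS1, the thalianol synthase, stood at 1.72 ± 0.12 and 2.42 ± 0.13, CYP708A2 (AT5G48000) at 1.41 ± 0.15 and 2.18 ± 0.15, and CYP705A5 (AT5G47990) at 1.76 ± 0.13 and 1.76 ± 0.13, all with adjusted p-values of 0.00212 or less. With AA at 3 h the calls of MRN1 (1.90 ± 0.53, adjusted p = 0.022) and CYP705A12 (1.76 ± 0.48, adjusted p = 0.0188) were lost with a library left out. These were wild-type replicates 2 and 3 and ein2-5 replicate 3 for MRN1, and wild-type replicates 1 and 2 and ein2-5 replicates 2 and 3 for CYP705A12 (highest adjusted p = 0.128 and 0.127). Of the 15 adjacent pairs these are 4. Others, such as AT5G46890 and AT5G46900 or AT1G05240 and AT1G05250, have values so alike that they may be 1 signal shared by both genes, which the random placements do not allow for. Why the pairs move together was not tested.

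Core hypoxia genes at 3 h of AA were also below untreated seedlings, a contrast that covering, time and batch share with AA, 16 of 27 lower and 6 higher in wild type (median -0.58, adjusted p = 0.00394, or 0.379 with an estimated correlation). In ein2-5, 15 were lower and 6 higher (median -0.67, adjusted p = 0.000628, or 0.335 with an estimated correlation). Untreated ein2-5 seedlings might also already lie along the AA response. Over the 3974 genes of the AA effect at 3 h, the mean signed score differed between untreated ein2-5 and wild type by -0.0379, less than the SD of 0.0611 among the ein2-5 libraries (exact permutation p = 0.4), which argues against it.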
